A study of Mus musculus with 20 samples.

How the data were processed

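Total RNA of liver and SAT was depleted of ribosomal RNA and sequenced, per the labels' protocols, from male C57BL/6J mice that had VAT removal or sham surgery at 8 to 9 months of age and ate a high-fat diet afterwards. The length of the diet is not given in the sources used here. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned with STAR 2.5.1a to GRCm38 and assigned to genes with featureCounts 1.46 of Subread. The gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here, so values of close paralogs, such as the cytochrome P450 and urinary protein genes, may share reads. The deposited table holds the authors' raw counts per gene, with no normalization, for 20 samples in 4 groups of 5.

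The table had 40757 entries under gene symbols. Of these, 317 were exact repeats of another entry (102 with any counts) and were dropped, and 117 symbols shared by 235 entries with different counts were kept apart by entry. Symbols turned into dates, 26 in all, were left as they were. Coordinates came from GENCODE M21 by symbol, which matched 40221 of 40322 distinct symbols. Total counts ran from 20307159 to 43618452 per library. Counting error is small for well-expressed genes but not for those near 0 CPM in a group, such as Igkv5-43 in VAT removed SAT (mean 0.0627 CPM) and Pla2g4f in VAT removed SAT (0.0457 CPM). Errors given are the SD between the 5 libraries of a group, or the SE of a log2 difference from the fit.

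Groups were taken from the sample titles. Liver and SAT were fitted separately in edgeR 4.0.16 under R 4.3.3, with filterByExpr by group, TMM normalization and a robust quasi-likelihood F-test of VAT removed against sham, and p was adjusted by Benjamini and Hochberg with a threshold of 0.05. The difference in response between tissues was tested in 1 fit of all 20 libraries with 4 group means. That fit, the exact permutation of score differences between tissues and the main pairs of splits treat liver and SAT libraries as separate mice, and whether equal numbers mark 1 mouse is not given in the sources used here. CPM values are TMM-scaled, apart from Alb and Adipoq in the account of the libraries, which are scaled by total counts, and log2 differences are VAT removed minus sham. The standard error comes from the quasi-likelihood F statistic. Tested on simulated counts with the same spread, the fit recovered 28.4%, 53.7% and 86.4% of liver genes changed 1.5-fold, 2-fold and 4-fold, and 10.4%, 38.8% and 86.4% in SAT, with 7 and 2 false calls. For the difference between the tissues it recovered 4.48%, 37.3% and 62.1%, with 4 false calls. The simulated genes were drawn independently of each other, without libraries in which many genes shift together. These percentages and false calls may therefore not hold for the real data.

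Before the data were examined, 33 gene lists of pathways, cell types and handling were fixed from textbook knowledge, with 26 tested in liver and 23 in SAT (at least 5 tested members each) and 17 in both. Each list was tested with camera at a preset correlation of 0.01, with the p adjusted over the lists of that tissue, and beside it with an estimated correlation, with fry, and by counting members that pass adjusted over the list alone. Without single libraries camera was run at the preset correlation alone. fry asks whether a list's genes move one way on balance, or in its mixed form whether they change in either direction, without comparing them with other genes. A list score is the mean log2 CPM of its members in a library. Exact permutation tests of scores used all 252 assignments of 10 libraries to 5 and 5, are two-sided, and can give 0.00794 as the smallest p.

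Named genes were also fixed by rule. They were the 8 largest increases and decreases among called genes with a mean of at least 1 CPM, or, with no called gene, the 3 smallest p in each direction as values only, without clone-style names. To these were added 14 metabolic genes in liver and 12 in SAT fixed by name, up to 4 members of each list with the smallest p, and the 5 largest differences in response each way, or the 3 smallest p each way where none passed. Of the genes this rule selected, 3 in SAT are withheld from the text and not reported here, and the search for single outlying libraries leaves them out. Agreement of the tissues was described by the correlation of log2 differences across genes and by Fisher's exact test of genes past an unadjusted p of 0.05.

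Alternatives set in advance were DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample weights, RLE and upper quartile normalization, no filter and a stricter one (1 CPM in 5 libraries), the test without robust fitting, 1 fit of all libraries, leaving out mitochondrial and the 20 most abundant genes, a log2 change of at least 1 besides the adjusted p, library number as a block, and leaving out each library in turn. Chosen after seeing the data were leaving out SAT sham libraries 3 and 4, alone or with SAT VAT removed library 2 or SAT sham library 5, leaving out sham library 5 in both tissues, and exact permutation of list scores. No library was left out of the results unless stated.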

Results

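RNA was sequenced from the liver and the subcutaneous adipose tissue (SAT) of male C57BL/6J mice whose epididymal visceral adipose tissue (VAT) had been taken out, or who had a sham operation with an incision alone, before they were given a high-fat diet. Each of the 4 groups of tissue and surgery had 5 libraries, 20 in total. Total counts of libraries 1 to 5 were 29040414, 34277426, 29053037, 33840496 and 32255433 in sham liver and 30667677, 34049582, 20307159, 26359022 and 37572706 in VAT removed liver. In SAT they were 33879293, 42235839, 30198306, 29409038 and 27411596 for sham and 31407440, 29664690, 43618452, 33045673 and 33235961 for VAT removed. Every library carried the marker of its own tissue. Alb, which encodes serum albumin, lay between 31710 and 54850 CPM (read counts scaled to library size) in the liver libraries and between 4.22 and 31.2 CPM in the SAT libraries. Adipoq, which encodes the fat hormone adiponectin, lay between 1105 and 2227 CPM in SAT and reached at most 0.359 CPM in liver.

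The liver comparison asks how hepatic transcription differs after VAT removal. Livers after VAT removal had more mRNA of several genes that respond to growth hormone and of some female-biased genes than sham livers. Socs2, a feedback inhibitor of growth hormone signalling, averaged 16.5 ± 6.81 CPM (SD, n = 5) after VAT removal and 4.86 ± 1.33 CPM in sham livers, a log2 difference of 1.77 ± 0.31 (SE). Cish, another feedback inhibitor of the same pathway, averaged 12.0 ± 5.05 CPM against 3.86 ± 0.906 CPM, a log2 difference of 1.63 ± 0.32. Both were above the sham mean in 5 of 5 VAT removed livers, but library 2, at 6.83 and 4.53 CPM, lay within the sham range, which reached 7.04 and 4.87 CPM. Cux2, a transcription factor gene that is female-biased in mouse liver, averaged 42.2 ± 51.8 CPM against 1.12 ± 0.284 CPM, with 124.7 CPM in VAT removed library 1 and 2.04 and 1.72 CPM in libraries 2 and 3. Its log2 difference of 5.24 ± 1.18 was 4.27 without library 1. Cyp2b13, a female-biased cytochrome P450 gene, averaged 138.1 ± 149 CPM against 4.80 ± 3.56 CPM, with 0.807 CPM in VAT removed library 3.

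Of the 17 measured members of the list of growth hormone dependent and sex-biased genes, 6 rose and 2 fell when p was adjusted over the list alone, while 0 passed over all genes tested in edgeR. The 6 were Socs2, Cish, Cux2, Cyp2b13, Igfals and Igf1, of which the last 2 encode a serum binding protein of insulin-like growth factors and the growth factor itself. Igf1 averaged 591.8 ± 102 CPM against 453.1 ± 72.5 CPM, and Igfals 97.7 ± 31 CPM against 58.5 ± 9.36 CPM. The 2 that fell were Mup20, a male-biased urinary protein gene, and Cyp2d9, a male-biased cytochrome P450 gene, at log2 differences of -2.18 ± 0.71 and -1.23 ± 0.45. Igfals, Mup20 and Cyp2d9 lay outside the rule for named genes and were chosen after their values were seen. Its members went both ways, and the list had a camera adjusted p of 0.224 (0.873 as the adjusted p with an estimated correlation) and an adjusted p of 0.013 in the fry test for change in either direction. Leaving out VAT removed liver library 2 made camera call the list at an adjusted p of 0.000179, with a median of 0.41, and leaving out library 3 gave a median of -0.11 at 0.0787.

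VAT removed liver library 3 stood apart from the other four in part of this list. Elovl3, a male-biased fatty acid elongase gene, was at 79.8 CPM in library 3, within the sham values of 37.1 to 94.6 CPM, and between 3.38 and 5.09 CPM in the other 4 VAT removed livers. Cyp2b9, a female-biased gene, was at 18.6 CPM in library 3 and between 321.3 and 613.3 CPM in the other 4. Hsd3b5 and Cyp7b1, both male-biased, were at 47.8 and 106.6 CPM in library 3, above the highest sham values of 1.23 and 62.7 CPM. Socs2 and Cish, at 15.4 and 18.6 CPM in library 3, lay with the other VAT removed livers. Elovl3, Cyp2b9, Hsd3b5 and Cyp7b1 were chosen after their values were seen. Without this library edgeR called 16 genes higher and 37 lower in liver, a count from a library set aside after its values were seen, and with all libraries Elovl3 had an adjusted p of 0.558.

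**Figure D1:**
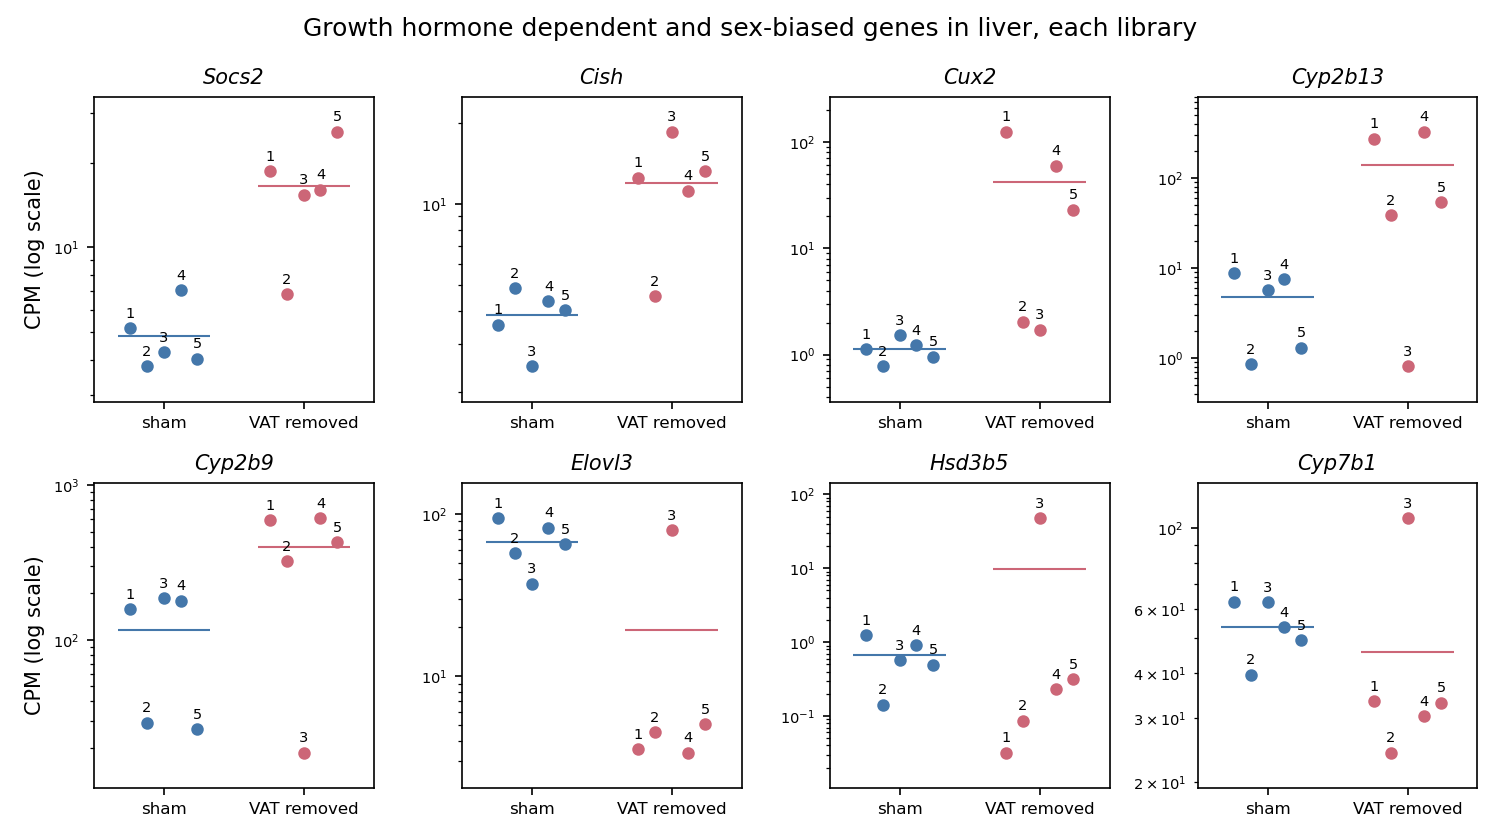
CPM on a log axis of 8 growth hormone dependent or sex-biased genes in each of the 5 sham and 5 VAT removed livers, with the library number at each point and a line at the arithmetic mean of each group. Socs2 and Cish were above the sham mean in 5 of 5 VAT removed livers, while library 3 had 79.8 CPM of Elovl3 against at most 5.09 CPM in the other 4.

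Across all 17078 genes tested in liver, edgeR called 0 higher and 0 lower, with 1691 genes at an unadjusted p under 0.05 where 854 would be so by chance on average. That number varies widely between groupings, and 5 of 100 random splits of the liver libraries, the real one included, gave as many. Smallest in adjusted p, at 0.0557 for each of 3 genes, were Ugt2b35 (a glucuronosyltransferase gene), Cbx7 (a Polycomb gene) and the clone-named 9130409I23Rik, which lies outside the rule for named genes. Ugt2b35 (chromosome 5, 87000860 to 87013275 in GRCm38) averaged 53.5 ± 6.21 CPM against 90.3 ± 10.1 CPM in sham, a log2 difference of -0.76 ± 0.10, and was below the sham mean in all 5 livers. Cbx7 (chromosome 15, 79915807 to 79971119) averaged 16.7 ± 1.65 CPM against 9.12 ± 1.41 CPM, a log2 difference of 0.87 ± 0.12, and was above it in all 5. Next in p came Lrp2bp at 1.08 ± 0.16 and Pced1b at 0.79 ± 0.13, and, with lower values, Aox1 (aldehyde oxidase) at -0.61 ± 0.10 and Ugt1a6b at -0.41 ± 0.07. DESeq2 called 84 genes higher and 108 lower, all of these 6 genes among them, as well as Socs2, Cish, Cux2 and Cyp2b13 at adjusted p of 1.08e-05, 0.000142, 0.000132 and 0.00558. limma-voom called 1 higher and 2 lower, and voom with sample weights 4 and 4.

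Genes of fat handling and glucose output that were fixed in advance did not pass in liver. Cd36 and Pparg differed by -0.05 ± 0.13 and -0.11 ± 0.17 on the log2 scale, and the lipid droplet genes Plin2, Cidec and Cidea by -0.14 ± 0.19, -0.44 ± 0.36 and -1.13 ± 1.17. Scd1, Fasn and Srebf1, genes of fatty acid synthesis, differed by 0.25 ± 0.25, -0.13 ± 0.35 and -0.02 ± 0.25. Pck1 and G6pc, which encode enzymes of glucose production, differed by 0.23 ± 0.26 and -0.39 ± 0.33. Fgf21 and Ccl2 differed by -0.46 ± 0.38 and -0.54 ± 0.48. Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis, averaged 106.1 ± 34.7 CPM against 67.9 ± 23.8 CPM and was above the sham mean in 5 of 5 livers, with an edgeR adjusted p of 0.467.

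Camera called 6 of the 26 lists tested in liver, and each lost its call with an estimated correlation, at an adjusted p of 0.873 for all 6. Interferon response genes fell, with 23 of 23 members lower, 14 of them at an unadjusted p under 0.05 and 0 adjusted over the list alone (median log2 difference -1.25, camera adjusted p = 2.45e-08). Rsad2 and Oasl1, antiviral genes, averaged 13.6 ± 3.47 and 20.1 ± 3.87 CPM after VAT removal against 70.5 ± 104.5 and 53.2 ± 49.5 CPM in sham. Sham liver 5 alone had 256.8 CPM of Rsad2, and without it the interferon median was -0.36 with a camera adjusted p of 6.53e-05. The acute phase list rose (median 0.15, camera adjusted p = 0.00166), with 14 of 22 members higher, 5 of them at an unadjusted p under 0.05. Adjusted over the list alone 1 member passed, Apcs (serum amyloid P) at 0.55 ± 0.14, and the metallothionein gene Mt1 differed by 1.43 ± 0.41. That list's median was 0.096 without sham liver 2, 0.27 without sham liver 5 and 0.097 without VAT removed liver 1, and camera called it in each case. The unfolded protein and integrated stress list fell (median -0.14, camera adjusted p = 0.012), with 16 of 19 members lower and Hspa5, a chaperone gene of the endoplasmic reticulum, at -0.37 ± 0.17. VAT removed liver 3 had 627.3 CPM of Hspa5 against at most 387.2 in its group, and without it the median was -0.26. That call ended without sham liver 5 (median -0.10, adjusted p = 0.0601) and without VAT removed liver 2 (-0.066, 0.172).

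Cell cycle genes fell in liver by camera (median -0.35, adjusted p = 0.00176), with 21 of 23 members lower and 0 passing adjusted over the list alone. Rrm2, a ribonucleotide reductase gene, averaged 6.15 ± 2.32 CPM against 12.2 ± 7.42 CPM. That call ended without sham liver 2 (-0.21, 0.0607), sham liver 5 (-0.22, 0.0611) or VAT removed liver 3 (-0.21, 0.119), and the median was -0.53 without sham liver 1. Kupffer cell markers rose by camera (median 0.51, adjusted p = 0.012), with 11 of 11 members higher and 0 passing adjusted over the list alone. Clec4f, a lectin gene of Kupffer cells, averaged 76.6 ± 22.5 CPM against 44.6 ± 15.8 CPM. Their median was -0.098 without VAT removed liver 1 (adjusted p = 0.255), 0.35 without sham liver 1 (0.132) and 0.40 without sham liver 3 (0.104). Endothelial markers rose by camera as well (median 0.17, adjusted p = 0.0295), with 12 of 15 higher and Stab2, a scavenger receptor gene of sinusoids, at 0.33 ± 0.12. That call ended without sham liver 1 (0.15, 0.132), sham liver 3 (0.11, 0.104), VAT removed liver 1 (0.13, 0.0628) or VAT removed liver 2 (0.12, 0.295). All 3 of these lists also had an adjusted p of 0.873 with an estimated correlation.

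Single members of several other liver lists passed adjusted over the list alone while the list itself had no camera call. In the circadian clock list, Per3 rose by 0.81 ± 0.23 on the log2 scale, Arntl (also called Bmal1) fell by 1.39 ± 0.39 and Clock by 0.34 ± 0.10, each with 5 of 5 livers on that side of the sham mean. That list had a median of 0.22 and a camera adjusted p of 0.195, or 0.0481 without sham liver 2, where its median was 0.24. In the xenobiotic list the glutathione transferase genes Gsta1, Gsta2 and Gstm1 fell by 1.83 ± 0.52, 1.11 ± 0.33 and 0.74 ± 0.23, and Cyp2b13 rose by 4.86 ± 1.25. For it, the median of -0.036 and the camera direction were negative and the mean of 0.129 was positive, at an adjusted p of 0.294 (0.0194 without VAT removed liver 4, with a median of -0.22). Irs2, an insulin receptor substrate gene, rose by 0.87 ± 0.19 in the list of glucose production and insulin signalling, which had a median of 0.11 and an adjusted p of 0.195. Cycs (cytochrome c) fell by 0.33 ± 0.07 in the oxidative phosphorylation list, where 25 of 30 members were lower with a median of -0.052 and an adjusted p of 0.0793. Camera called that last list without VAT removed liver 4 (-0.088, 0.00346), VAT removed liver 5 (-0.061, 0.0422) or sham liver 5 (-0.11, 6.79e-05).

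Lipid lists had no camera call in liver with all libraries. Calls without single libraries rest on the preset correlation of 0.01, where that estimated with all libraries was 0.827 for cholesterol synthesis. Lipogenesis and triglyceride synthesis had a median of 0.12 (adjusted p = 0.752), lipid droplet and fatty acid uptake -0.072 (0.294), and fatty acid oxidation 0.035 (0.265), the last called without VAT removed liver 3 (0.085, 0.00785) or sham liver 4 (0.060, 0.0494) and at -0.030 (0.881) without sham liver 5. The lipogenesis median was -0.015 (0.297) without VAT removed liver 2. Acot3, a PPAR-alpha target, averaged 85.1 ± 66.8 CPM against 13.3 ± 10.0 CPM. Cholesterol synthesis had a median of 0.049 (0.605), and was called higher without VAT removed liver 3 (0.17, 0.0219) or sham liver 3 (0.35, 0.000859), while its median was negative without sham liver 2 (-0.087, 0.408) or 5 (-0.074, 0.646), or VAT removed liver 2 (-0.088, 0.732) or 5 (-0.107, 0.527). Bile acid synthesis and transport had -0.071 (0.196), and was called lower without VAT removed liver 3 (-0.19, 0.000186) or sham liver 5 (-0.13, 0.031). For Abcb4, the canalicular phospholipid transporter gene, the values were 328.1 ± 39.1 CPM against 421 ± 33.6 CPM. The lipoprotein list had a median of -0.002 with a mean of 0.065 and a positive camera direction (0.605).

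Other cell types and handling lists had no camera call in liver with all libraries. Calls without single libraries, given below, rest on the preset correlation of 0.01. The correlations estimated with all libraries were 0.648 for cholangiocyte, 0.504 for stellate and 0.592 for matrix genes, so these calls are weak. Macrophage and inflammation genes had a median of -0.30 (adjusted p = 0.252), and were called lower without sham liver 1 (-0.42, 0.0313) or sham liver 4 (-0.37, 0.0385), while without sham liver 5 the median was 0.068 (0.646). Extracellular matrix had 0.12 (0.387), and was called higher without VAT removed liver 1 (0.28, 0.0218) or sham liver 5 (0.29, 0.011), while its median was -0.153 (0.295) without VAT removed liver 2, and 0.011 and 0.039 without sham liver 1 or 4 (0.953 each). Cholangiocyte markers had 0.40 (0.0793), and were called higher without VAT removed liver 1 (0.53, 0.000982), 3 (0.54, 0.00801) or 4 (0.50, 0.048), or sham liver 2 (0.54, 0.0481) or 5 (0.47, 0.0361). Hepatic stellate markers had 0.19 (0.0603), and were called higher without VAT removed liver 1 (0.31, 0.000253) or 3 (0.24, 0.0219), or sham liver 2 (0.20, 0.0223). Lymphocyte markers had 0.27 (0.195), and were called higher without VAT removed liver 4 (0.30, 0.0194) or sham liver 5 (0.50, 0.011). Erythroid genes had -0.054 (0.294), and were called lower without VAT removed liver 2 (-0.31, 0.000138) or 3 (-0.011, 0.042). Adipocyte markers had a median of 0.031 and a mean of 0.112 with a negative camera direction (0.958). Mitochondrially encoded genes had 0.068 (0.329) and immediate early genes -0.11 (0.605), and without sham liver 5 these medians were -0.015 (0.69) and 0.158 (0.453). Of the neutrophil markers 3 of 11 were tested in liver, and of the pancreatic acinar markers 0 of 13, too few for a list test.

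The SAT comparison asks how the remaining subcutaneous depot differs after VAT removal. In SAT after VAT removal camera called extracellular matrix genes higher and interferon response genes lower, and list medians differed most for genes of lymphocytes and of skeletal muscle. Both calls were lost with an estimated correlation (adjusted p = 0.686 for each), and the matrix call also without sham libraries 3 and 4 (0.127). Thbs2, a matrix glycoprotein gene, averaged 273.7 ± 47.4 CPM (SD, n = 5) against 142.4 ± 54.8 CPM, and Col1a1, the main collagen gene, 2753 ± 545.9 CPM against 1869 ± 399.4 CPM, each above the sham mean in 5 of 5 libraries. Zbp1, a nucleic acid sensor gene of the interferon response, averaged 9.21 ± 3.42 CPM against 16.6 ± 5.36 CPM and was below the sham mean in 5 of 5. Ms4a1, a B cell gene, averaged 0.636 ± 0.182 CPM against 27.4 ± 36.4 CPM in sham, where libraries 3 and 4 had 64.3 and 69.9 CPM and the other 3 at most 1.10 CPM.

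Lymphocyte and lymph node markers fell in SAT, with 20 of 20 members passing adjusted over the list alone against 0 over all genes tested (median log2 difference -4.18, camera adjusted p = 1.36e-10). That call was lost at an adjusted p of 0.686 with an estimated correlation. Mean log2 CPM of the list was 5.86 and 5.84 in sham libraries 3 and 4 and between -0.08 and 0.79 in the other 8. Without these 2 libraries, an alternative chosen after seeing the data, the median was 0.22 with a camera adjusted p of 0.44. Cell cycle genes moved with the lymphocyte genes. They fell by camera with 23 of 23 members lower (median -0.47, adjusted p = 0.000199, and 0.922 as the adjusted p with an estimated correlation), 0 of them passing adjusted over the list alone. Their median was -0.23 without sham library 3 (adjusted p = 0.0949) and 0.11 without sham libraries 3 and 4 (0.166). Without sham library 5 as well camera called the list higher (0.18, 0.0488), which was lost with an estimated correlation (0.869). Pcna and Bub1, genes of replication and of the spindle checkpoint, differed by -0.23 ± 0.09 and -0.82 ± 0.38.

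Skeletal muscle markers rose by camera in SAT (median 3.43, adjusted p = 0.000431, and 0.922 as the adjusted p with an estimated correlation), with 15 of 17 members higher and 0 passing adjusted over the list alone. VAT removed library 2 had the highest list score, 10.4 on the log2 CPM scale, followed by sham library 2 at 7.33 and VAT removed library 1 at 6.09. Neb, which encodes the sarcomere protein nebulin, was at 3810 CPM in VAT removed library 2 and 279.1 CPM in sham library 2. Without VAT removed library 2 the list median was -0.096 with a camera adjusted p of 0.32, without sham library 2 it was 6.91 with 2.22e-07, and without sham libraries 3 and 4 it was 2.84 with 0.0596.

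**Figure D2:**
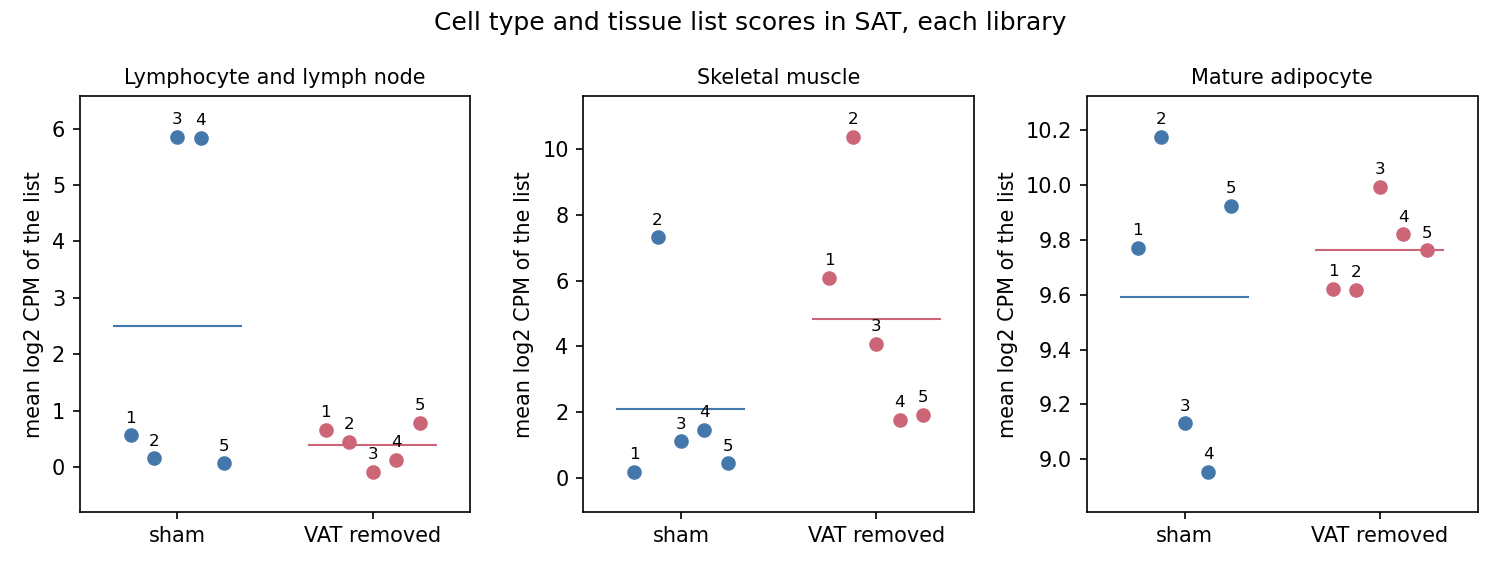
Mean log2 CPM of the lymphocyte and lymph node, skeletal muscle and mature adipocyte lists in each of the 5 sham and 5 VAT removed SAT libraries, with the library number at each point and a line at each group mean. Sham libraries 3 and 4 had lymphocyte scores of 5.86 and 5.84 and the lowest adipocyte scores, and the muscle score was highest, 10.4, in VAT removed library 2.

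Extracellular matrix genes rose by camera in SAT with 26 of 28 members higher, 7 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.27, camera adjusted p = 6.99e-09, and 0.686 as the adjusted p with an estimated correlation). Thbs2, Eln (elastin) and Col6a2 differed by 0.94 ± 0.26, 0.47 ± 0.13 and 0.45 ± 0.15. Leaving out sham libraries 3 and 4, rich in lymphocyte markers, brought the matrix median to 0.094 with an adjusted p of 0.127. Endothelial markers rose by camera with 12 of 15 higher (median 0.24, adjusted p = 0.00106, and 0.686 as the adjusted p with an estimated correlation), Vwf and Flt1 by values of 0.48 ± 0.18 and 0.43 ± 0.16. Their median was 0.15 without sham library 2, 0.37 without sham library 5, and 0.17 without sham libraries 3 and 4, where the adjusted p was 0.0686. Camera called them without VAT removed library 2 as well (0.21, 0.0226) and without sham library 5 instead (0.42, 7.85e-05), at 0.795 and 0.667 with an estimated correlation.

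Interferon response genes fell by camera in SAT with 22 of 23 members lower, 8 of those at an unadjusted p under 0.05 (median -0.65, adjusted p = 3.18e-07, and 0.686 as the adjusted p with an estimated correlation). Adjusted over the list alone 1 member passed with all libraries, 15 lower and 1 higher without sham libraries 3 and 4 (median -0.87), 0 without these and VAT removed library 2 (-0.75), and 5 lower without sham libraries 3, 4 and 5 (-0.36, camera adjusted p = 2.63e-09). With an estimated correlation the adjusted p was 0.708, 0.632 and 0.784 in these 3 settings. Zbp1 and Usp18 differed by -0.85 ± 0.27 and -0.64 ± 0.23, and Cxcl10, a chemokine gene, was the 1 member with a higher mean, at 0.38 ± 0.12. Sham library 5 had the highest interferon score, 5.35 against 3.73 to 4.29 in the other sham libraries, and without it the median was -0.26 with a camera adjusted p of 0.0166.

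**Figure D3:**
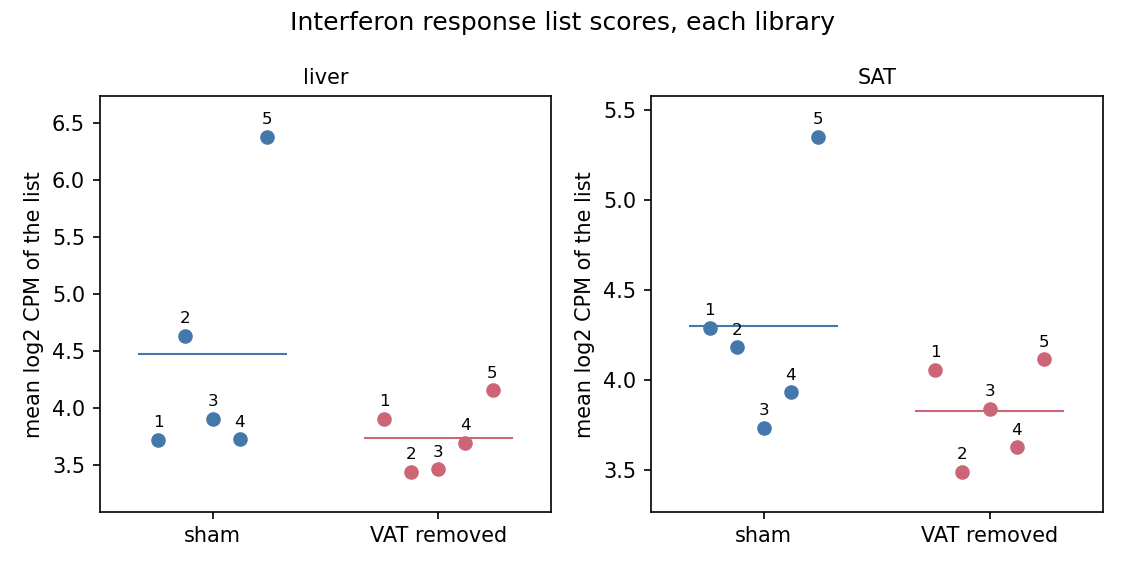
Mean log2 CPM of the interferon response list in each library of liver and of SAT, with the library number at each point and a line at each group mean. Sham library 5 had the highest score in both tissues, 6.38 in liver and 5.35 in SAT.

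Lipogenic and adipocyte genes were slightly higher in SAT after VAT removal, and these differences turned with the lymphocyte-rich libraries. Lipogenesis and triglyceride synthesis rose by camera (median 0.11, adjusted p = 0.0362, and 0.922 as the adjusted p with an estimated correlation), with 15 of 22 members higher and 1 passing adjusted over the list alone, the elongase gene Elovl6 at 0.58 ± 0.13. Mature adipocyte genes rose by camera with 20 of 23 higher (median 0.11, adjusted p = 0.0491, and 0.922 as the adjusted p with an estimated correlation) and 0 passing adjusted over the list alone, Aqp7 (a glycerol channel) at 0.33 ± 0.18. Without sham libraries 3 and 4 the medians were -0.075 (0.323) for lipogenesis and -0.19 (0.000292) for adipocyte genes, each at 0.761 with an estimated correlation. The lipogenesis call ended without sham library 3 (0.023, 0.322) or 4 (0.035, 0.333), or VAT removed library 2 (0.036, 0.108), 3 (0.011, 0.241) or 5 (0.12, 0.0656), and its median was 0.18 without sham library 2. The adipocyte call ended without sham library 3 (0.005, 0.655) or 4 (-0.042, 0.971), or VAT removed library 3 (0.054, 0.289), 4 (0.094, 0.0748) or 5 (0.11, 0.0656), and its median was 0.23 without sham library 2 and 0.19 without sham library 5.

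Other SAT lists had no camera call with all libraries. Where a call without a single library is given, it rests on the preset correlation of 0.01 alone. Fatty acid oxidation genes had a median of 0.037 (adjusted p = 0.238), or 0.15 without sham library 2 (0.0107), and -0.071 (0.889) and -0.082 (0.946) without sham library 3 or 4. Oxidative phosphorylation genes had 0 (0.67), or 0.10 without sham library 2 (0.0115), and -0.099 (0.0904) and -0.086 (0.17) without sham library 3 or 4. Without sham libraries 3 and 4 camera called both lower, at -0.22 (0.00117) and -0.21 (2.09e-10), and each call was lost with an estimated correlation (0.761). Cholesterol synthesis had 0.083 (0.238), with 1 member passing adjusted over the list alone, and the list was called without VAT removed library 4 (0.13, 0.00248) and at 0.016 (0.947) without sham libraries 3 and 4. Glucose production and insulin signalling had 0.029 (0.295), and was called without sham library 2 (0.11, 0.026) and at -0.078 (0.166) without sham libraries 3 and 4. Macrophage and inflammation had 0.041 (0.306), and was called without sham library 1 (0.11, 0.00784). The circadian list had 0.16 (0.0598), and was called without VAT removed library 1 (0.18, 0.0228) or 3 (0.18, 0.0469), or sham library 2 (0.22, 0.0107) or 3 (0.11, 0.0489). The unfolded protein list had 0.013 (0.67), thermogenic genes -0.017 (0.935), immediate early genes 0.019 (0.67), epithelial markers 0.16 (0.722), hepatocyte markers 0.17 (0.67) and erythroid genes -0.13 (0.67). Some of these medians turned without 1 library, to -0.032 and -0.043 for the unfolded protein list (without sham library 3 or VAT removed library 5), 0.099 for thermogenic genes and 0.127 for erythroid genes (each without sham library 5), and -0.095 and -0.119 for immediate early genes (without sham library 2 or VAT removed library 4). The thermogenic median was also above 0 without sham library 2 (0.05) or VAT removed library 1 (0.062), 4 (0.034) or 5 (0.006). Progenitor and fibroblast markers had a median of 0.015 with a mean of -0.108 and a negative camera direction (0.722). Mitochondrially encoded genes had -0.082 (0.589), and were called lower without VAT removed library 3 (-0.28, 0.0134) or sham library 3 (-0.21, 0.0404), while their median was above 0 without sham library 2 (0.076, 0.735) or VAT removed library 1 (0.03, 0.903) or 4 (0.017, 0.854). Without sham libraries 3 and 4 camera also called thermogenic (-0.24, 0.0446), progenitor (-0.24, 1.08e-05), erythroid (-0.47, 0.00149) and mitochondrially encoded genes (-0.36, 8.83e-05) lower, calls lost with an estimated correlation at 0.708 for progenitor and 0.761 for the other 3 lists. In the neutrophil list (median 0.28, 0.889), 1 of 5 members passed adjusted over the list alone, S100a8 at -0.85 ± 0.27.

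Across all 18530 genes tested in SAT, edgeR called 0 higher and 0 lower, with a smallest adjusted p of 0.431 and 1973 genes at an unadjusted p under 0.05 where 926 would be so by chance on average. As many were given by 27 of 100 random splits of the SAT libraries, the real one included, so this is no sign of an excess. DESeq2 called 49 higher and 150 lower, and limma-voom 0 with or without sample weights. Smallest in p among genes with higher values were Lmcd1 (0.53 ± 0.10), Synpo (0.55 ± 0.11) and Plxna4os2 (0.71 ± 0.14), and among those with lower values Lypd6b (-1.20 ± 0.21), the immunoglobulin segment Igkv5-43 (-5.54 ± 1.00, at most 0.122 CPM in each VAT removed library) and the interferon-induced gene Samd9l (-0.55 ± 0.11). DESeq2 called all 6 of these. Lmcd1 (chromosome 6, 112273758 to 112330425 in GRCm38) averaged 14.1 ± 1.01 CPM against 9.73 ± 1.01 CPM. Without sham library 5 edgeR called 0 genes higher and 1 lower, and without sham libraries 3 and 4 it called 0 and 0.

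Adipose genes fixed in advance did not pass in SAT. Lep (leptin) and Adipoq differed by 0.06 ± 0.17 and 0.21 ± 0.24 on the log2 scale, Pparg and the glucose transporter gene Slc2a4 by 0.16 ± 0.16 and 0.11 ± 0.28, and Irs1 by 0.46 ± 0.24. Fasn and Scd1 differed by 0.10 ± 0.23 and 0.54 ± 0.27. Inflammatory genes gave -1.27 ± 0.63 for Tnf, 0.12 ± 0.35 for Ccl2 and 0.23 ± 0.23 for the macrophage gene Adgre1. Tnf was at 8.48 and 8.04 CPM in sham libraries 3 and 4, and its log2 difference without them was 0.013. Ucp1, the uncoupling gene of brown fat, had 283 counts over the 10 SAT libraries, did not pass the filter on low counts and was not tested.

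The third comparison asks whether the response to VAT removal differed between SAT and liver. Socs2 again stood out, as the value was higher after VAT removal in liver and lower in SAT. It averaged 19.9 CPM in VAT removed liver against 5.90 in sham liver, and 8.52 CPM in VAT removed SAT against 11.6 in sham SAT, in the joint fit of both tissues. Its difference in response, SAT minus liver, was -2.21 ± 0.42 on the log2 scale. Il18, a cytokine gene, and Pla2g4f, a phospholipase gene, had differences of -1.10 ± 0.23 and -7.80 ± 1.62, the latter from means of at most 1.59 CPM. Tubb4b (a tubulin), the imprinted RNA Meg3 and Pi4k2b (a lipid kinase) had positive differences of 1.04 ± 0.20, 1.34 ± 0.28 and 0.52 ± 0.11.

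None of these passed in edgeR, which called 0 of 19954 genes (smallest adjusted p 0.246, 2021 genes at an unadjusted p under 0.05), while DESeq2 called 127, all 6 named ones included, and limma-voom 0. The edgeR count was 1 without sham liver 2, 3 without VAT removed liver 3 and 1 without sham SAT 5. Of the 17 lists tested in both tissues, 0 differed in response by an exact permutation test of the list scores, with the adjusted p at 0.979 for each. Scores of the interferon list differed by -0.74 in liver and -0.47 in SAT (unadjusted exact permutation p = 0.721 for the difference), and those of the lymphocyte list by 0.18 and -2.11 (0.177). These tests treat liver and SAT libraries as separate mice, although some may come from the same mouse.

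Across the 15978 genes tested in both tissues, the log2 differences in liver and SAT had a Pearson r of 0.0156 and a Spearman rho of 0.0521, and 50.5% had the same sign. These are correlations across genes, which are not independent replicates. Without sham library 5 in both tissues, an alternative chosen after seeing the data, r was -0.0847. Among genes at an unadjusted p under 0.05, 58 were higher in both tissues where 29.8 would be by chance (two-sided Fisher's exact p = 1.17e-06 over genes), and 44 were lower in both where 52.8 would be (0.215). Higher in liver and lower in SAT were 55 against 45.2 (0.134), and lower in liver and higher in SAT 24 against 34.8 (0.0611).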

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

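Chosen only after the result was seen were the tests on sham library 5 and on the macrophage share, that on the adipocyte share, the splits that keep libraries of the same number together, and those for genes lower in both tissues. Each of 352 sets of 5 libraries, for a named gene, a list score or a measure of the library, was searched for 1 library far from the other 4, by the gap to its neighbour divided by the whole range, with 0.71 as the critical value. Chance alone sets apart about 1 in 20 such sets, here 18, and 27 were found.

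Interferon response genes were lower after VAT removal in liver and SAT, and sham library 5 stood far above its group for Ifit1 (gap 0.781) and Isg15 (0.827) in liver and for Usp18 (0.725) in SAT. A raised interferon level in the mouse or mice behind sham number 5 may account for the difference: without it the medians were -0.361 in liver and -0.258 in SAT, and the exact permutation p of the list score was 0.349 and 0.262, while camera adjusted p were 6.53e-05 and 0.0166. These tests leave that explanation open, since the difference was smaller but on the same side without the library, and in SAT also without sham libraries 3, 4 and 5 together (-0.36, with 2 sham libraries left). A lower share of macrophages is not excluded in liver either, with an exact permutation p of 0.0794 for the interferon score minus the Kupffer score. While Kupffer markers had a higher median, this was -0.098 without VAT removed liver 1, and the macrophage and inflammation list had a lower one (-0.303). That lower median turned positive without sham liver 5. In SAT the macrophage and inflammation list had a median of 0.041, with 15 members higher and 12 lower, against -0.648 for the interferon list. Chance is not excluded for the list calls, as 27 of 100 splits of the liver libraries gave a camera p as small as the real 9.434e-10 (smallest of the others 6.852e-21) and 22 of 100 in SAT as small as 4.152e-08 (5.37e-23), and an effect of VAT removal also stays open.

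Lymphocyte genes were lower after VAT removal in SAT, and this rested on sham libraries 3 and 4, whose scores exceeded the median of the other 3 sham libraries by 5.69 and 5.68 on the log2 scale. A lower share of adipocytes, which would raise all other cell types alike, is argued against by macrophage and endothelial scores that were higher by at most 0.397 and 0.198 in these libraries. Lymph node tissue in those 2 pieces of SAT is a candidate source, since Glycam1, Chst4, Madcam1, Cxcl13 and Coch, genes of lymph node vessels and stroma outside the list, had a median rise of 4.48 and 4.228 over the other sham libraries in sham 3 and 4. These medians are those of Madcam1 and Chst4, counted from a floor of -4.06 log2 CPM, so their size depends on that floor. Glycam1 rose by 4.952 and 5.05, but Cxcl13 by 2.443 and 2.776 and Coch by 0.783 and 1.346. Cxcl13 was at 4.525 in sham 3 and already at 3.748 in sham 2. Other lymphoid tissue in fat with such vessels and stroma stays open. Adipocyte scores in them lay at -0.793 and -0.969 from the same median. In 16 of 100 splits of the SAT libraries the list had a camera p as small as the real 5.915e-12 (smallest of the others 2.103e-15), so chance is not excluded, and no biological explanation was tested, since the design names none for 2 libraries of 1 group.

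VAT removed liver library 3 stood apart from its group, high for Elovl3 (0.872), Hsd3b5 (0.78), Cyp7b1 (0.781), Hspa5 (0.758) and Manf (0.731) and low for Cyp2b9 (0.815) and Plin2 (0.794). Its lower depth is argued against, since thinning the other VAT removed livers to it moved the log2 CPM of 5 such genes by at most 0.595. As to another time of day, library 3 lay outside the others' range in 9 of 19 clock genes while 2 other libraries did so in 11 each. By the rule set in advance this count goes against that explanation. However, the count ignores the direction of each gene and takes the other libraries as collected alike, so it does not decide. A sham library under a VAT removed label may be the explanation: on 178 genes picked without it, its position between the sham mean (0) and the VAT removed mean (1) was 0.083, where held-out sham livers lay from -0.026 to 0.39 and the other VAT removed livers from 0.45 to 1.10. The positions of these other livers rest on different sets of 30 to 82 genes, each picked with library 3 in the VAT removed group, so they are not on the same scale of genes. The Socs2 and Cish of library 3, at 15.4 and 18.6 CPM, and its Hsd3b5 and Cyp7b1 lay above the sham range, but these 4 genes were set beside the explanation after their values were seen and decide nothing, so a mouse that responded otherwise stays open, and no biological explanation was tested. Without this library edgeR called 53 liver genes, which only the real grouping reached among 60 splits of the other 9 (highest of the others 6). Chance is excluded for that count as it stands, but the library was singled out among 10 after its effect was seen, which the splits do not allow for.

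Other single libraries stood apart as follows. In liver, sham library 2 was low for Fgb (0.795) and Plin2 (0.878), sham library 1 was high for Psmc2 (0.777), VAT removed library 2 was low for Igfals (0.836), and VAT removed library 5 was high for Psmd14 (0.816). In SAT, sham library 2 was high for Neb (0.759), Ryr1 (0.724) and the muscle score (0.822), and sham library 5 for Flt1 (0.754). VAT removed SAT library 2 was high for Eln (0.767), Myl1 (0.782), the share of counts in the 10 most abundant genes (0.725) and the share in genes overlapping ribosomal RNA (0.783). VAT removed SAT library 4 was high for Pcna (0.784), library 3 was low for Peg3 (0.725) and high in total counts (0.744), and library 1 was high for the neutrophil score (0.728).

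Random splits of the libraries into groups of the same sizes were refitted to see how often chance gives results as large. The real grouping is counted as one of the splits here and above. In liver, all 100 splits gave at least the 0 genes of edgeR (highest of the others 6), 5 of 100 gave the 1691 genes at an unadjusted p under 0.05 (highest 2637), 4 of 40 gave the 192 genes of DESeq2 (879), and 95 of 100 gave the 6 called lists (18). In SAT, all 100 gave at least 0 genes (5), 27 of 100 gave 1973 genes at an unadjusted p under 0.05 (5036), 8 of 40 gave the 199 genes of DESeq2 (1542), and 80 of 100 gave the 8 called lists (16). For the difference between tissues, all 50 gave at least 0 genes (2), and 11 of 50 gave 2021 at an unadjusted p under 0.05 (3085). In 85 of 100 pairs of splits the correlation between tissues was as far from 0 as 0.0156 (0.269). The comparisons with 0 genes could not have come out otherwise, since no split can give fewer, and they decide nothing. For the other results so far, chance is not excluded. The 58 genes higher in both tissues were reached in 4 of 100 pairs of splits (highest of the others 91). All pairs but the real one kept the same sham liver on the VAT removed side, so higher and lower were not interchangeable in them. That comparison therefore does not decide whether chance gives 58. The 44 lower in both were reached in 14 of 100 (387), and chance is not excluded for them. With same-numbered liver and SAT libraries put on the same side, as they would be if they shared mice, 92 of 100 splits gave a correlation as far from 0 as 0.0156 (0.265). In these splits, where the 2 sides were also swapped at random, 2 of 100 gave the 58 genes (69) and 6 of 100 the 44 genes (76). In this setting chance is excluded at 5% for the 58 genes taken alone, but not for the 44 or the correlation. The 2 counts of genes that went opposite ways were not set against splits. Some splits called several times the real count, such as 1542 genes with DESeq2 in SAT, where edgeR called at most 5 in the other splits. Whether structure among the samples other than the surgery or the DESeq2 test itself gave such DESeq2 counts was not tested. For edgeR in SAT, the counts at an unadjusted p under 0.05 went with the lymphocyte list, as read after the splits were run. Splits with a camera p of that list of at most 7.852e-08, the real one included, had 1207 to 5036 such genes. The other splits, at a camera p of at least 0.3104, had at most 773.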

How the results depend on the processing

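Alternatives that left out SAT sham libraries 3 and 4 (alone, or with VAT removed library 2 or sham library 5), sham library 5 in both tissues, and the exact permutation of list scores were chosen after seeing the data, and all others were set before. Over all alternatives 120 counts stayed within 1.5 times, 25 were higher by more than that and 6 lower. Of the values of single genes 5500 kept their direction and side of the threshold, 74 passed it and 111 changed direction without a call in either fit. Of the list results 593 kept both, 52 gained a call and 74 lost it. Another 67 changed direction without a call in either fit, and 18 changed direction with a call in the main or the alternative fit.

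In liver, genes higher and lower numbered 84 and 108 with DESeq2, 1 and 2 with limma-voom, with no filter or with the stricter filter, 4 and 4 with voom and sample weights, and 16 and 11 with all 20 libraries in 1 fit, where RLE, upper quartile, the fit without robust estimation and leaving out abundant genes gave 0 and 0. Leaving out 1 library at a time gave 0 to 16 higher and 0 to 37 lower, from VAT removed library 3, with 1 higher without VAT removed library 1 and 2 without library 2, and 5 to 11 called lists (11 without VAT removed library 3, 10 without library 4). In SAT, DESeq2 gave 49 and 150, all other tools and filters 0, and leaving out 1 library 0 higher and 0 to 1 lower. The difference between tissues had 127 genes with DESeq2 and 0 to 3 without 1 library. Lists called by camera fell to 0 in both tissues with an estimated correlation, with fry and by exact permutation, which allow for members that move together. Adjusted over all lists, exact permutation could pass only if several lists had its smallest p, 0.00794, so its 0 decides little. Unadjusted, the lowest exact permutation p among lists called by camera were 0.0952 for acute phase genes in liver and 0.0556 for matrix genes in SAT. DESeq2 differs from the other tools in its dispersion shrinkage and test, and the cause was not tested.

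Several SAT lists reversed without sham libraries 3 and 4, where medians were -0.075 for lipogenesis, -0.224 for fatty acid oxidation, 0.111 for cell cycle, -0.21 for oxidative phosphorylation, -0.191 for adipocyte and 0.218 for lymphocyte genes. Without VAT removed library 2 as well these were -0.175, -0.247, 0.001, -0.248, -0.182 and 0.169, with -0.808 for muscle, and without sham library 5 as well lipogenesis, oxidation, cell cycle, phosphorylation and adipocyte medians were -0.117, -0.201, 0.176, -0.228 and -0.203, with cell cycle called higher (0.0488). The muscle median was still 2.836 without sham libraries 3 and 4 alone, and turned negative without VAT removed library 2 alone. The correlation between tissues was -0.0847 without sham library 5 in both. At this depth genes near 0 CPM in a group, such as Igkv5-43 in VAT removed SAT, rest on few reads.

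With library number as a replicate block edgeR again called 0 genes in each tissue, with 1760 in liver and 1298 in SAT at an unadjusted p under 0.05, and camera called 8 lists in each. Liver gained the macrophage (-0.231, adjusted p = 0.0126) and stellate (0.184, 0.0209) lists, and SAT gained the circadian list (0.217, 0.0221) and had lipogenesis at 0.112 (0.0692). With each number of a surgery group as a block across tissues, 0 genes differed in response. Residual correlations of same-numbered sham and VAT removed libraries ran from -0.055 to 0.198 in liver and from -0.237 to 0.322 in SAT, over 0.1 in 4 of 5 liver pairs and 2 of 5 SAT pairs. The number's own partner was the best match of 3 of 5 sham livers and 1 of 5 sham SAT libraries, a hint in liver at most, so the samples are taken to share only a number. Same-numbered liver and SAT libraries had correlations from -0.18 to 0.108 in sham and from 0.038 to 0.101 in VAT removed mice, with the own number as the best match in 0 of 5 and 3 of 5, which leaves open whether they share mice.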

Other observations

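Every test in this part was chosen only after the result was seen, since its gene list was written after the genes called by DESeq2 had been read. Each test leaves out the members that DESeq2 called, but this does not make it independent. The other members were measured in the same libraries and may move with the called ones. The p values also do not allow for the other lists that could have been written. Imprinted genes, expressed from 1 parental copy, had higher values in SAT after VAT removal in 24 of 26 measured members, with a median log2 difference of 0.446. Zim1, Peg3, Plagl1 and Peg10 differed by 1.84 ± 0.43, 1.24 ± 0.37, 1.13 ± 0.30 and 0.87 ± 0.19, and Meg3 by 0.61 ± 0.21. Of the 21 members that DESeq2 did not call, 19 had higher values, and their score differed at an exact permutation p of 0.00794, the smallest possible, with a camera p of 0.0227 with an estimated correlation. Without sham libraries 3 and 4 the exact permutation p of these 21 was 0.0536 where 0.0179 is the smallest possible, and without VAT removed library 2 as well it was 0.0571, so the difference did not pass in either case. A shared rise of imprinted genes in SAT is a hypothesis from these data that may rest in part on tissue composition.

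Genes of the 26S proteasome, the cell's main protein degradation complex, had lower values in liver after VAT removal in 32 of 32 members, with a median of -0.185. Psmd14, Psmd7 and Psmc2 differed by -0.32 ± 0.07, -0.29 ± 0.06 and -0.28 ± 0.06. The 27 members not called by DESeq2 were all lower, at an exact permutation p of 0.00794, which is the smallest possible, with a camera p of 0.0409 with an estimated correlation. The exact permutation p was again 0.00794 without VAT removed library 3, and 0.0286, also the smallest possible, without sham library 5 as well. Targets of NRF2, the regulator of antioxidant and detoxifying genes, had lower values in 33 of 36 members with a median of -0.393, Gsta1, Gsta2, Gstm1, Ugt2b35, Ugt1a6b and Aox1 included. Their 25 members not called by DESeq2 gave an exact permutation p of 0.0794, which did not pass, and a camera p of 0.0449 with an estimated correlation, which did, so a shared shift stays open. The exact permutation p was 0.135 without VAT removed library 3 and 0.286 without sham library 5 as well. A lower proteasome programme in liver after VAT removal is a hypothesis that would need other samples to test.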
